A study of Homo sapiens with 4 samples.

How the data were processed

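RNA labelled as from MCF-7 cells, an oestrogen receptor positive luminal breast cancer line, was measured on 4 one-colour arrays of 60-base probes, 2 per group. Per the labels, 1 group carried a retroviral vector with the precursor of the microRNA miR-374a and the other the empty vector. Virus came from 293FT packaging cells. Cells were infected for 24 hours with polybrene at 2.5 μg/mL and then kept in puromycin at 1.5 μg/mL for 10 days. The series' design text calls the 2 samples of a group biological replicates. Groups and replicate numbers were taken from the sample titles.

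Per the file headers, each array was scanned in Cy3 and read with Agilent Feature Extraction 10.5.1.1. The deposited spot intensity is linear, background-subtracted and detrended within 1 array, and was not scaled between arrays; the raw mean spot signal and the local background stand beside it. The deposited value table holds log2 values of the same arrays. Each of the 4 columns has a mean of 8.41, an SD of 3.94 and quartiles of 5.07, 8.40 and 11.41, as columns after quantile normalization would, and the columns correlate at 0.998 to 0.999 with log2 of each array's own processed signal. Its scale, direction and quantile step were read from the values, since the sources used here do not name that step. The table differed from quantile normalization of the processed signals by 0.33 on the log2 scale (root mean square) on each array.

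Of 43376 non-control spots, 80.5% to 81.5% per array were well above background by the scanner software's flag, and 0 were saturated. The 75th percentile of the signal was 2702 and 3402 on the vector arrays, and 3646 and 3805 on the arrays labelled miR-374a. The number of arrays limits the precision.

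Values were log2 of the processed signal minus the log2 of each array's 75th percentile over non-control spots without an outlier flag. Control spots were dropped and flagged spots were set to missing. Spots of 1 probe were averaged. Of 41000 probes, 131 for Y-linked and X-inactivation transcripts were left out, and 118 lacked a usable spot on at least 1 array. Of the remaining 40751, the 33939 well above background on both arrays of a group were tested. Symbols came from a RefSeq gene table of GRCh38.p14, used for names only. It named 25312 probes through an accession, 2504 through a current symbol and 782 through a synonym; 12271 stayed without a name and are not named here. A gene took the value of its tested probe with the highest mean signal over the 4 arrays. There were 16104 such genes, 6410 of them with over 1 tested probe. In 176 genes the probes that passed disagreed in direction. Probe positions are those of the array files, on hg18.

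Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Every p-value printed for a gene is this adjusted p. The p-values measure the spread between 2 arrays per group. A second rule counted genes at least 2-fold apart whose groups did not overlap. For a gene with no probe well above background on any array of 1 group, the fold is a lower bound. The bright group's mean is set against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. That floor is not a limit of detection for each probe, so the bound is approximate. For CDH2 the probe's own signal was the higher, and the bound equals the measured fold of 189.

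The choice of samples, tests, alternatives, named genes and 23 gene lists was made before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Named were the 12 highest and 12 lowest differences among genes past the threshold, above background on all 4 arrays and without overlap; up to 4 per direction below background in 1 group, by size of the bound; 14 genes fixed by name; and 2 to 4 members per list with the largest differences among those past the threshold. The fixed names are PTEN, WIF1, WNT5A, CDH1, CDH2, VIM, FN1, CTNNB1, SNAI1, SNAI2, TWIST1, ZEB1, ZEB2 and FTX. Further lists were written after the first fit. They hold genes of the regions 17q23 and 20q13 that MCF-7 is known to carry amplified, CDKN2A and MTAP, which lie in a region that MCF-7 is known to lack, and markers of glia, neurons, melanocytes, hepatocytes, muscle and kidney tubule. Random lists for the amplified regions, 10000 in number, were matched on mean signal.

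Alternatives were normexp background correction with an offset of 50, quantile and median scaling, the deposited table, 2 other filters on dim probes, a replicate block, another variance model, an ordinary two-sample test, the mean over a gene's probes, and each array left out. Added after seeing the data was normexp with a trended, robust variance model. The analysis of genes by miR-374a seed sites in 3' UTRs was planned and needs sequences; it was not analysed here. All arrays lay on 1 slide and came from 1 scan, so a slide block had nothing to separate.

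The fit was tested on simulated data drawn from the real probe means and spreads, for the comparison of the 2 groups over 33939 probes. With 200 probes changed, it recovered 0% of 2-fold, 34.3% of 4-fold and 74.2% of 16-fold changes. With 16970 probes changed, it recovered 78.3%, 92.8% and 98.1%, and 3.02% of calls were false. Each simulated probe had the same spread in both groups. Real spreads could differ, as for CDH1, with an SD of 0.0076 in vector and 3.25 on the arrays labelled miR-374a. The simulated rates therefore do not carry over to genes with unequal spread. Of 20 unchanged lists of 40 probes camera called 0, and it called the 1 list shifted by 1 on the log2 scale. In that simulation probes varied independently and none outside the shifted list changed. It therefore cannot show how often camera calls falsely where genes of a list vary together. The estimated correlation was 0.72 in the real epithelial list and 0.33 in the oestrogen response list.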

Results

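Expression was measured on 2 arrays labelled as MCF-7 cells transduced with a miR-374a precursor and 2 labelled as MCF-7 with the empty vector, to ask which genes move with the microRNA and whether markers of epithelial-mesenchymal transition, the passage of epithelial cells to a fibroblast-like state, are among them. Across 40751 probes the vector arrays correlated with each other at 0.99 and the arrays labelled miR-374a at 0.985. Between groups the correlation was 0.876 to 0.878 for replicate 1 of the arrays labelled miR-374a and 0.912 for replicate 2. The SD of the difference between replicates was 0.47 on the log2 scale in vector and 0.68 in the other group. These correlations are across probes, which are not independent replicates.

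The arrays labelled miR-374a differed from vector in 48.6% of the genes tested. Of the mesenchymal list 35 of 48 genes rose, of the epithelial list 27 of 43 fell and of the oestrogen response list 30 of 45 fell. With an estimated correlation none of these 3 lists passed (camera, adjusted p = 0.358, adjusted p = 0.732 and adjusted p = 0.705). That version also raised p for lists with an estimated correlation under the preset 0.01. A miss there does not by itself show that correlated genes made a call. Of 16104 genes, 3437 rose and 4396 fell past the limma threshold; by probe, 7645 rose and 8470 fell of 33939. At least 2-fold apart without overlap were 2569 higher and 2921 lower genes. No overlap was seen in 83.0% of all genes, where random splits of 2 against 2 give 33.3%. The median difference of all genes was −0.18 on the log2 scale, from −0.04 with normexp to −0.21 with median scaling. With normexp 0 probes passed (limma, lowest adjusted p = 0.196), 5273 had an unadjusted p under 0.05, and 1675 genes were at least 2-fold higher and 1859 lower. Lower genes past the threshold numbered 1845 without vector replicate 1 and 1660 without vector replicate 2, and 38 and 40 of the genes that the naming rule takes then lost their call, while 3030 and 3001 genes were at least 2-fold lower. With 1 vector array left, the spread comes from the arrays labelled miR-374a alone.

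E-cadherin (CDH1), the adhesion protein of epithelial cells, measured 5.68 ± 0.01 (SD, n = 2) in vector. On the arrays labelled miR-374a it measured −1.90 and 2.69. This gap of −5.28 ± 1.57 (SE) did not pass the threshold (limma, adjusted p = 0.0520). N-cadherin (CDH2), which replaces it in mesenchymal cells, was at least 189-fold higher (adjusted p = 0.000237) and not well above background in vector. The filament protein vimentin (VIM) rose by 8.58 ± 0.36 (SE), 383-fold (adjusted p = 0.000438), and its second probe by 9.39. The repressors of CDH1 split. ZEB1 was at least 12.4-fold higher (adjusted p = 0.000552), ZEB2 rose 24.1-fold (0.00431), SNAI2 4.08-fold (0.00297) and TWIST1 2.56-fold (0.00500), while SNAI1 fell 6.33-fold (0.0415). Fibronectin (FN1) rose by 0.93 at its brightest probe (adjusted p = 0.0282), and its other 2 probes, at 0.04 and 0.60, did not pass. Beta-catenin (CTNNB1), the effector of Wnt signalling, rose 2.15-fold (adjusted p = 0.00976) at its brightest probe, and by 1.77 (adjusted p = 0.00534) and 2.77 (adjusted p = 0.000887) at the other 2.

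**Figure D1:**
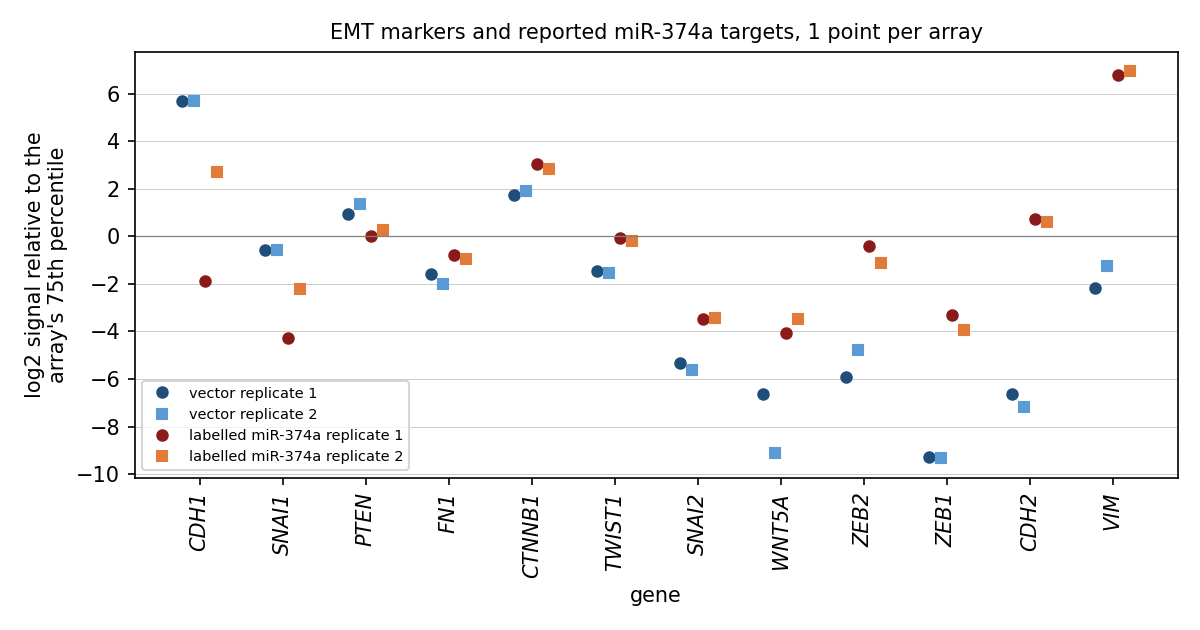
Each point is 1 array; the vertical axis is log2 signal relative to the array's 75th percentile and the horizontal axis names the gene. For CDH1 the arrays labelled miR-374a lie at −1.90 and 2.69, and both vector arrays lie at 5.68 to 5.69.

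PTEN, WIF1 and WNT5A are known as reported targets of miR-374a. PTEN, the phosphatase that opposes AKT signalling, fell by 1.01 ± 0.22 (SE; limma, adjusted p = 0.0239), a 2.01-fold difference; the probe lies on chromosome 10 between 89707697 and 89707756 (hg18). Its other probes measured −0.68 (adjusted p = 0.0220) and −0.53, which did not pass (adjusted p = 0.0547). WNT5A, a secreted Wnt ligand, rose by 4.08 ± 0.88 (SE; adjusted p = 0.0239), but was well above background on only 1 vector array. WIF1, a secreted Wnt inhibitor, was not tested, since each of its 2 probes was well above background on 1 vector array and on 0 arrays labelled miR-374a. No probe carried the name FTX, the host transcript of the microRNA.

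Among genes above background on all 4 arrays, the highest differences belonged to AKR1B1, an aldose reductase (11.53 ± 0.15 SE; limma, adjusted p = 0.000135; chromosome 7, 133782637 to 133780601 on hg18 as the files give it), the matrix protein FBLN1 (11.35 ± 0.18) and the neuronal ubiquitin hydrolase UCHL1 (10.98 ± 0.16). The glutathione transferase GSTP1 (10.08), the matrix protein SPARC (10.01) and the phospholipid-binding protein ANXA1 (9.80) followed, then DPYSL3 (9.65), DKK3 (9.29), SCRG1 (9.17), SCHIP1 (9.13), SCN4B (9.07) and PLAT (8.86). In vector AKR1B1 (−6.34 and −6.23), FBLN1 (−6.02 and −6.27) and PLAT (−6.51 and −6.28) lay near the lowest signals well above background, −7.05 and −7.45. Such sizes depend on the background subtraction, which the SE does not cover. With normexp the median size of the 933 genes over 16-fold apart went from 5.37 to 3.11. CXCL14, a chemokine, was not well above background in vector and was at least 12321-fold higher. IGFBP7 was at least 7170-fold, AKR1B10 at least 6189-fold and LIMCH1 at least 3626-fold higher. By the probe used for each gene, 513 genes were well above background on both arrays labelled miR-374a and on neither vector array.

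Among genes past the threshold and above background on all 4 arrays, the lowest differences were those of the cadherin CDH18 (−6.64 ± 0.93 SE; limma, adjusted p = 0.00861), PKIB (−6.27), SLC24A3 (−6.20), AGR2 (−6.19), MSMB (−6.17), MGP (−6.12) and the oestrogen receptor ESR1 (−6.05 ± 1.42 SE; adjusted p = 0.0291; chromosome 6, 152465601 to 152465660 on hg18). GCHFR (−6.00), DSCAM (−6.00), SGCG (−5.85), SYTL2 (−5.82) and NIPAL2 (−5.80) made up the 12. ESR1 lay at −7.06 on replicate 1 of the arrays labelled miR-374a, the lowest signal well above background on that array. On replicate 1 of the arrays labelled miR-374a these 12 genes lay below replicate 2 by between −2.69 (CDH18) and −4.67 (SLC24A3). Their differences ran from −5.29 to −3.84 without that replicate 1 and from −8.54 to −7.42 without replicate 2. The calls were kept in these fits, where the spread came from the vector arrays alone, so keeping them is no sign of robustness. They were lost without vector replicate 1 or 2, at differences from −6.91 to −5.72 and from −6.75 to −5.32. There the spread came from the arrays labelled miR-374a alone. SPOCD1, at least 37.1-fold lower, WNT2B (at least 30.5-fold), KLK12 (at least 28.8-fold) and COX7B2 (at least 24.0-fold) were not well above background on the arrays labelled miR-374a. By the probe used, 307 genes were on in vector only. A further 113 genes were over 16-fold lower and did not pass.

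Of 48 mesenchymal genes tested 35 rose, 6 fell, SNAI1 and COL3A1 among them, and 7 did not pass, and 36 rose adjusted over the list alone; the median was 4.62 (camera, adjusted p = 4.38e-10, and adjusted p = 0.358 with an estimated correlation). CALD1, an actin-binding protein, was at least 2747-fold higher, the gap junction protein GJA1 at least 1407-fold, the membrane linker MSN at least 964-fold and CCN2, a matrix protein, at least 575-fold. Of 43 epithelial genes 27 fell, 2 rose and 14 did not pass, CDH1 among these, with 37 lower adjusted over the list alone, and a median of −3.34 (camera, adjusted p = 8.16e-05, and adjusted p = 0.732 with an estimated correlation). The protease inhibitor SPINT1 fell by 5.23, the transcription factor OVOL1 by 5.21, RAB25 fell by 4.92 and the tight junction protein CLDN3 fell by 4.72. Of 45 oestrogen response genes 30 fell, 3 rose and 12 did not pass, 37 fell adjusted over the list alone, and the median was −3.61 (camera, adjusted p = 0.000255, and adjusted p = 0.705 with an estimated correlation). The progesterone receptor PGR fell by 8.07 and AGR3 fell by 7.28, sizes that are uncertain since both were well above background on only 1 of the 2 arrays labelled miR-374a. In the epithelial and oestrogen lists the arrays labelled miR-374a stood apart from each other, replicate 1 lying below replicate 2 by a median of −2.06 and −1.60.

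**Figure D2:**
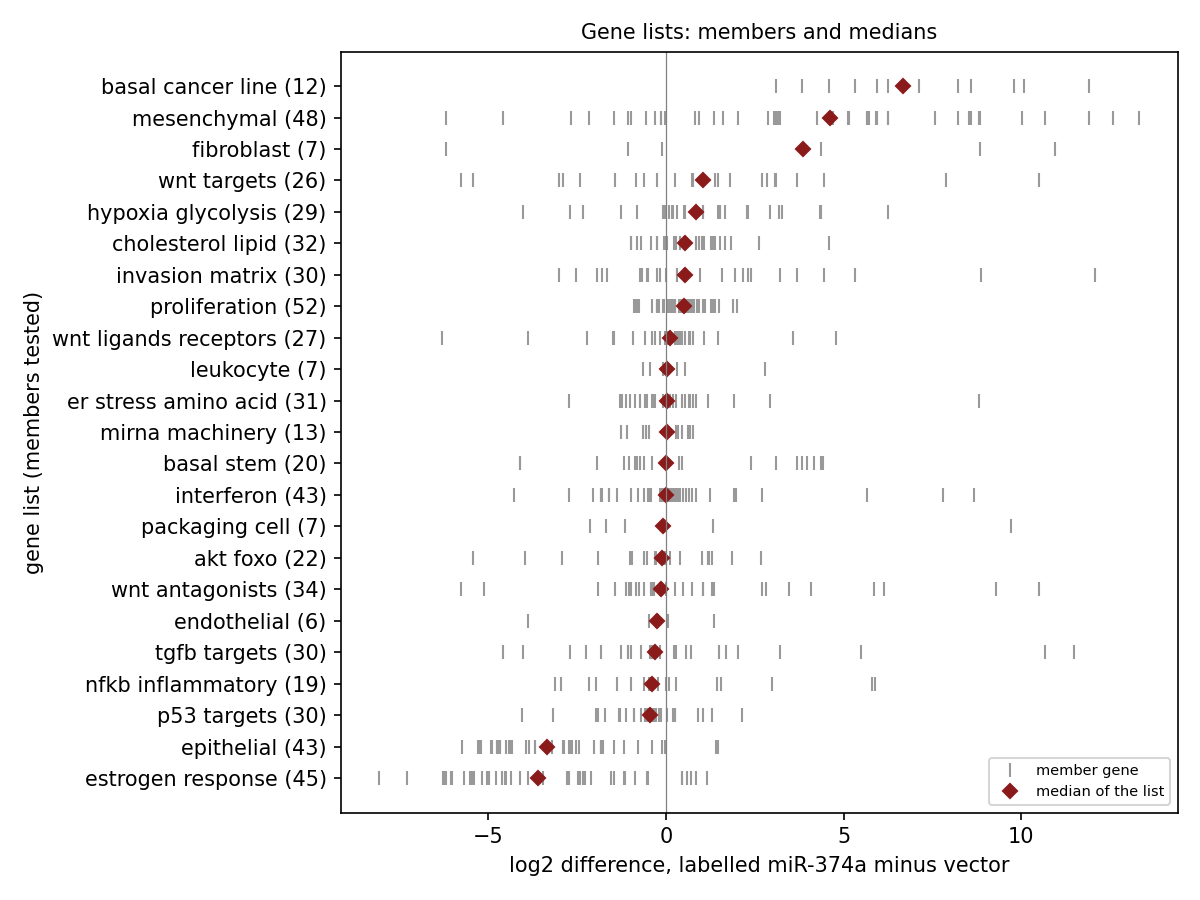
Ticks are the log2 differences (horizontal axis) of single genes and diamonds the medians, for each list (vertical axis, members tested in brackets). The mesenchymal median is 4.62, the epithelial −3.34 and the oestrogen response −3.61.

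Of 26 Wnt target genes 16 rose, 6 fell and 4 did not pass, 16 rose adjusted over the list alone, and the median was 1.03 (camera, adjusted p = 0.00564, and adjusted p = 0.538 with an estimated correlation). APCDD1, itself an inhibitor of Wnt signalling, was at least 1150-fold higher, TNFRSF19 at least 59.7-fold and the protease MMP7 at least 5.34-fold, while the transcription factor ASCL2 fell by 5.42. Without replicate 2 of the arrays labelled miR-374a this list missed the threshold (adjusted p = 0.0511). Wnt antagonists went both ways, 13 up, 9 down and 12 not past the threshold of 34 (13 up adjusted over the list alone), with a median of −0.14, a mean of 0.83 and no call (camera, adjusted p = 0.404). DKK3, SFRP1 (6.13) and SOSTDC1 (at least 45.5-fold) were higher. Of 27 Wnt ligands and receptors 6 rose and 6 fell (adjusted p = 0.404), with WNT5B at least 27.5-fold higher and FZD8 11.8-fold higher, and ROR2 lower, well above background on only 1 array labelled miR-374a.

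Of 52 proliferation genes 19 rose, 4 fell and 29 did not pass, with a median of 0.51 (camera, adjusted p = 0.000496, and 0.538 as the adjusted p with an estimated correlation). TOP2A, the mitotic topoisomerase, rose 3.97-fold and CENPF 3.67-fold. Of 29 hypoxia and glycolysis genes 14 rose, 5 fell and 10 did not pass, led by the carbonic anhydrase CA9 at 76.2-fold and EGLN3 at 20.7-fold (median 0.85, camera adjusted p = 0.00190, and 0.705 as the adjusted p with an estimated correlation); ANGPTL4 fell 16.2-fold. Of 32 cholesterol and lipid genes 16 rose, 4 fell and 12 did not pass, with higher values for the desaturase FADS2 at 23.9-fold and STARD4 at 6.09-fold (median 0.53, camera adjusted p = 0.00355, and 0.724 as the adjusted p with an estimated correlation). Of 30 invasion and matrix genes 14 rose, 4 fell and 12 did not pass, with osteopontin (SPP1) at least 3050-fold and PLAU 40.1-fold higher (median 0.53, camera adjusted p = 0.0134, and 0.538 as the adjusted p with an estimated correlation).

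The remaining pathway lists held members that went both ways and had no camera call. Of 43 interferon genes 11 rose, TRIM22 at least 179-fold, and 12 fell, IRF7 19.6-fold (adjusted p = 0.789). Of 19 inflammatory genes 5 rose, TNFAIP2 59.3-fold, and 4 fell, ICAM1 8.69-fold (adjusted p = 0.879). Of 22 AKT and FOXO genes 7 rose, IRS2 6.42-fold, and 7 fell, INPP4B 43.0-fold (adjusted p = 0.879). Of 30 TGF-beta targets 7 rose, ITGB8 at least 1340-fold, and 9 fell, TGFBI 24.2-fold (adjusted p = 0.841). Of 30 p53 targets 4 rose and 12 fell, GDF15 16.7-fold (adjusted p = 0.245). Of 31 stress and amino acid genes 6 rose, PSAT1 450-fold, and 6 fell, SESN2 2.43-fold (adjusted p = 0.795). Of 20 basal and stem cell genes 8 rose, SOX2 21.6-fold, and 8 fell, CDH3 17.4-fold (adjusted p = 0.315). Of 13 genes that make and load microRNAs 2 rose, DROSHA 1.71-fold, and 3 fell, AGO2 2.15-fold (adjusted p = 0.936).

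Lists of markers of other cells were also tested, and camera called 1 of them. All 12 tested markers of basal or mesenchymal breast cancer lines rose, with a median of 6.68 (camera, adjusted p = 1.67e-09, and 0.358 as the adjusted p with an estimated correlation), GSTP1 among them. Of 7 fibroblast markers tested 4 rose, COL1A2 459-fold, and 2 fell, with COL3A1 at least 18.7-fold lower (adjusted p = 0.149). Of 7 packaging cell markers 2 rose, CDH6 at least 484-fold and NEFL 2.52-fold, and 3 fell, LHX1 4.39-fold (adjusted p = 0.936). Of 7 leukocyte markers 1 rose, CSF1R 6.96-fold, and 1 fell, CD79A 1.56-fold (adjusted p = 0.795). Of 6 endothelial markers CDH5 rose 2.54-fold (adjusted p = 0.936). In the chromosome regions 17q23 and 20q13, known to be amplified in MCF-7, 21 of 22 tested genes fell and 0 rose, with a median of −2.21, below the lowest of 10000 random lists (−1.26). BCAS3 fell by 4.51 and TBX2 by 3.35, and BCAS4, at 0.27, did not pass.

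**Figure D3:**
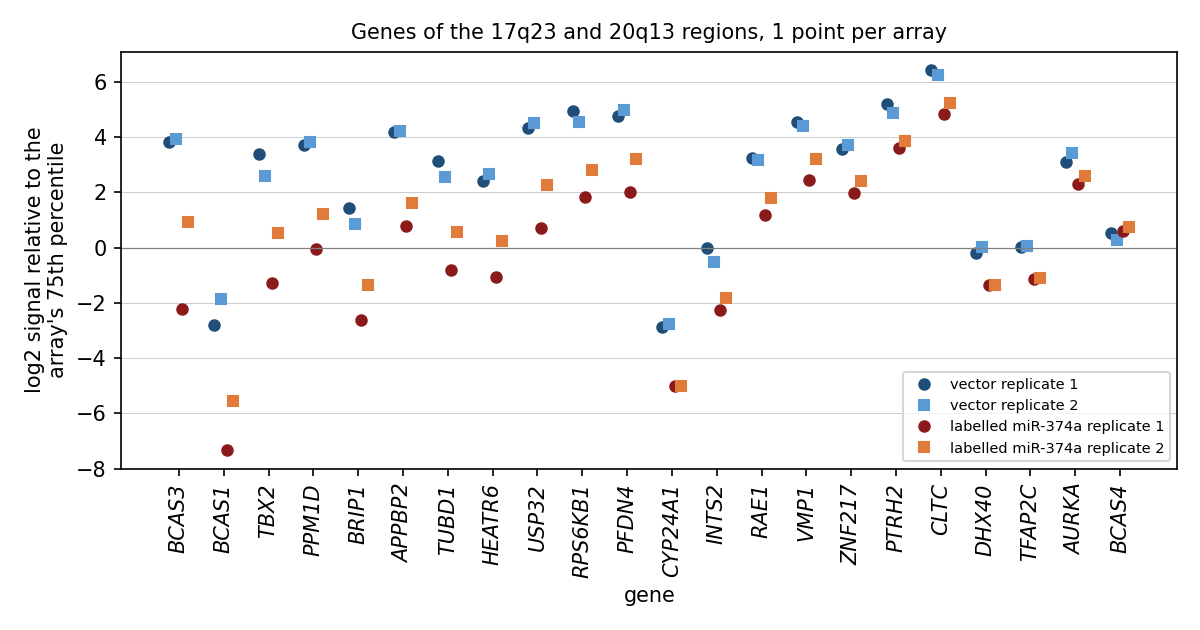
Each point is 1 array; the vertical axis is log2 signal relative to the array's 75th percentile and the horizontal axis names genes of the regions 17q23 and 20q13. The median difference is −2.21, and BCAS4 (0.27) is the exception.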

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

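The normexp fit with a trended, robust variance model was chosen after seeing the data. No alternative turned a direction past the threshold. Counts run probes higher and lower, then genes higher and lower. Normexp gave 0, 0, 0 and 0 past the threshold and 1675 higher and 1859 lower genes at least 2-fold apart; the prior degrees of freedom were 1.37 against 2.31. With the trended, robust model, normexp gave 3494, 3787, 2093 and 2533, and the size counts were again 1675 and 1859. The ordinary two-sample test gave 1695, 824, 857 and 386. An adjusted p under 0.01 left 4133, 2574, 1910 and 1325, and at least 2-fold with the adjusted p left 5134 lower probes and 2630 lower genes. With 1 array left out, the lone array assumed to vary like the other group, lower probes numbered 3316 to 6691 and lower genes 1660 to 3470, lowest without vector replicate 2 (3316 and 1660; without vector replicate 1, 3580 and 1845). Higher calls made up 43.9% of called genes, 68.9% with the ordinary test and 55.9% and 58.6% without vector replicate 1 or 2; the cause was not tested. With an estimated correlation the epithelial (median −3.34, adjusted p = 0.732), mesenchymal (4.62, 0.358) and Wnt target (1.03, 0.538) lists missed the threshold. For the Wnt targets that correlation was −0.019, below the preset 0.01, yet the unadjusted camera p went from 0.00196 to 0.0743. For the invasion and matrix list it was 0.0091, and the unadjusted camera p went from 0.00526 to 0.106. Correlation between genes does not account for those misses. It was 0.72 in the epithelial list, far above the preset value. Fry tests a list against no change and not against other genes, so its calls answer another question; with it the epithelial list missed (−3.34, 0.0952) and the Wnt antagonists passed (median −0.14, mean 0.83, adjusted p = 0.000808). Of 9 lists called by camera, 0 passed with an estimated correlation. Fry lost 3 of them, the others besides the epithelial list being oestrogen response (adjusted p = 0.0560) and cholesterol (0.0675). It gained 8, among them interferon (0.000574), fibroblast (0.000808), basal and stem cell (0.00850), and TGF-beta, p53 and packaging cell (0.0283 each). Over leave-one-out fits the Wnt target median was 0.98 to 1.03. Replicate numbers were shared as numbers only (correlation of deviations 0.124); with the replicate block 7260 genes passed against 7833, 6923 of them shared. Quantile, median scaling and the deposited table gave 16704, 16208 and 16891 probes against 16115. The seed site analysis and the slide block were not run. Per array 80.5% to 81.5% of spots stood well above background. Of 40751 probes 33939 were tested, and those not tested have no estimate. Bounds were given only for tested genes with no probe well above background in 1 group.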

Other observations

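Tests on scaling, on normexp and its trended, robust fit, on the share of luminal RNA, on 1 luminal source and on glial markers were chosen after the first fit was seen. The gene lists for the amplified regions and for CDKN2A and MTAP were also written after the first fit. Of 16 glial markers 13 were tested and 11 rose on the arrays labelled miR-374a, GPM6B 354-fold higher (3.44 against −5.02), SLC1A3, a glutamate transporter, 133-fold, GFAP, the astrocyte filament, 70.1-fold and SOX2 21.6-fold. SLC1A2, another glutamate transporter, fell 14.8-fold. Of the 13 tested, 9 were also well above background on both vector arrays, and SOX2 is in the basal and stem cell list too. By the probe used, 3 were on only on the arrays labelled miR-374a. These were OLIG1, with the largest difference of the glial list (376-fold), OLIG2 (at least 4.55-fold) and S100B (at least 6.48-fold). Of other markers, 3 of 10 neuronal, 2 of 7 muscle, 1 of 7 melanocyte, 1 of 7 kidney tubule and 0 of 7 hepatocyte genes rose and were well above background on both arrays.

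Many probes differed between the groups. Scaling did not lower the count (16208 to 16891 probes by quantile, median or deposited values, against 16115), but normexp did, to 0. That fit also starts from the raw mean signal with an offset of 50, and with a trended, robust variance model the same values gave 3494 higher and 3787 lower probes. Of 933 genes over 16-fold apart 82.0% stayed at least 2-fold apart without overlap, with median sizes of 5.37 before and 3.11 after. The median residual SD was 0.18 before and 0.51 after and the prior degrees of freedom 2.31 and 1.37; which of these ended the calls was not isolated. RNA of packaging cells is argued against, with 2 of 10 markers higher, where 7 were tested and 3 of these fell. Fry called that list (adjusted p = 0.0283), but it tests against no change and the members went both ways. RNA from cells other than MCF-7 may contribute, as the amplified regions' median of −2.21 lies below the random lists' 5th percentile of −0.47, and this was 1 of the 2 things the test asked for. The other, MTAP or CDKN2A on only in the arrays labelled miR-374a, was met by 0 genes when all probes of a gene were counted. Along MTAP towards CDKN2A its 3 probes, starting at 21792766, 21827969 and 21852980 on hg18, were 1.47, 5.0 and 7.66 higher. The last was on only there and meets the criterion by itself, and the others were also on in vector. A deletion in the vector cells that ends within MTAP would give this order, a reading made after the values were seen. The criterion was written for genes and names no probe, which leaves MTAP open. Of CDKN2A, 1 probe was on in vector, with a difference of −1.19, and the other on 1 vector array. Signal for CDKN2A on the vector arrays puts either the premise that MCF-7 lacks it or the specificity of that probe in doubt, so CDKN2A decides nothing. For a change within MCF-7 the test asked that neither gene be well above background on the arrays labelled miR-374a. That was not met, as all 3 MTAP probes and 1 CDKN2A probe were on there on both arrays. Of these only the last MTAP probe was off in vector, so the miss shares the doubt about the premise. A change within MCF-7, which includes loss of amplified copies, and other cells therefore cannot be told apart from these tests. The groups' differences are not attributed to miR-374a here.

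The 2 arrays labelled miR-374a differed in luminal genes. KRT8, KRT18, KRT19, EPCAM and CDH1 stood at a median of 18.3% of their vector signal on replicate 2 (12.6% to 42.6%) and 0.757% on replicate 1. A different share of luminal RNA could account for this: it would lower the 513 genes whose probe was on only on these arrays by −0.29 on replicate 2, and the median was −0.25 (−0.19 unscaled to −0.30 with quantile). The match is coarse. The quartiles of these 513 genes were −0.45 and −0.01, and the share ran from 12.6% to 42.6% over the marker genes. The rule also allowed a margin around the predicted value. A single luminal source like the vector cells would give 1 ratio to vector for all its genes, and over 386 genes high in vector and at least 8-fold lower on replicate 1 the log2 ratio had a median of −2.65 and an interquartile range of 0.757, under the limit of 1 set for it. Both values are consistent with replicate 2 holding vector-like RNA that replicate 1 largely lacks; a mixed culture, carry-over or cells at different stages of change were not tested apart.

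Genes of other tissues were on in the arrays labelled miR-374a. Cells of a glial type could have brought them, and 68.8% of the glial markers were higher and well above background there. The test asked for a larger share than in every other cell type list, and the basal or mesenchymal breast cancer line list had 12 of 12, against 4 of 10 for fibroblasts, so glial cells were not singled out. VIM and CD44 of the basal list are known in glial cells too, which weakens the comparison.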
